A study of Rattus norvegicus with 9 samples.

How the data were processed

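RNA from pancreatic islets of Wistar rats was measured on Affymetrix Rat Genome 230 2.0 arrays, 1 array per sample. The labels place 4 samples in a lean group fed standard chow and 5 in an obese group fed a cafeteria diet for 30 days. The islets were freed by collagenase digestion, per the labels' protocols, and the RNA was extracted with Trizol, amplified and labelled with biotin in vitro. Each sample is titled as a rat, and the labels do not say whether islets of several animals were pooled, so the p-values measure the spread between these 9 samples. The hour of killing, the feeding state, the hybridization date and any batch are not given in the sources used here.

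The deposited table holds log2 expression values per probe set. The submitters' processing notes name RMA, R 2.7.0 and affy 2.0.1 without saying which step used which. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of each set on the log2 scale, so a shift shared by most genes of a group would be removed by it. The column medians of the deposited log2 values lay between 5.28 and 5.32, and single values between 2.44 and 14.24. RMA values carry no detection call, and small differences of dim probe sets are compressed. The number of arrays limits the precision: the median standard error of a difference between the groups was 0.0981 log2, and the median 95% interval reached 0.217 log2 (1.16-fold) to either side. No 2 arrays held identical values.

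The table had 31099 probe sets. The 57 control probe sets were left out of the gene tests, which left 31042. The platform annotation listed 21262 of these. It gave 20826 a single gene (14217 genes) and 436 several genes, and 9780 were not listed; both of these kinds are called unnamed here. Of the single-gene probe sets, 20758 were found in a RefSeq gene table by gene identifier, and 0 symbols changed. Where a gene had several probe sets, the probe set with the highest mean over the 9 arrays stood for it, and probe sets with the opposite sign are mentioned beside named genes.

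The main test was limma 3.58.1 (R 4.3.3), lmFit with plain eBayes on the values as deposited, two-sided, without covariates, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. All differences are cafeteria diet minus chow on the log2 scale, given with the moderated standard error (SE). Before the data were examined, 27 gene lists with 800 entries were fixed, covering the cell types of islets and of the tissue around them and pathways of diet, growth and stress. Of the entries 720 were measured. The Reg family list had 4 measured members, under the minimum of 5, so 26 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each list also had its members counted over all genes and adjusted over the list alone, and a score per array, the mean over its members of the difference from the 9-array mean. Scores and the control probe sets for RNA quality (3-prime minus 5-prime difference of actin and Gapdh) were compared by a two-sided exact permutation test over the 126 splits of the arrays into 4 and 5, whose smallest possible p is 0.00794. Principal components and correlations between arrays were computed over the tested probe sets, and relations between scores and RNA quality were tested by exact permutation (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3; plots with matplotlib 3.10.9).

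The genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 genes per direction with the largest change among genes past the threshold with separate groups, filled up by the smallest unadjusted p where fewer passed, skipping locus-number symbols (0 among the higher and 1 among the lower genes). It always took Ins1, Ins2, Gcg, Sst, Ppy, Iapp, Pdx1, Mafa and Slc2a2, and 1 item that is not reported here. It also took the 4 members with the smallest unadjusted p of each called list and of each of 9 cell type lists. This named 95 genes. Genes outside the rule are said to have been chosen after their values were seen.

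The tests were tested on simulated data with the means and spreads of these arrays. Among 31042 simulated probe sets, 200 were changed. The test recovered 43 of 67 changed by 1.5-fold, 64 of 67 changed by 2-fold and 62 of 66 changed by 3-fold, and 4 of its 173 calls were false. These shares hold for 200 changed probe sets with independent noise of equal spread in both groups. They do not give the share that would be found on the real arrays. A list shifted by 0.2 log2 was called as the only 1 of 26 lists, but the simulated genes were independent, which real genes are not.

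The alternatives were median centring, repeated quantile normalization, a filter on dim probe sets, an intensity trend with robust variances, array weights, the acinar score or the RNA quality as a covariate, an adjusted p of 0.10, other rules for several probe sets of a gene, an estimated correlation in camera, fry, the exact test of list scores, and leaving out each sample in turn. After the data were seen, fry in either direction, leaving out lean replicates 1 and 3 together, the B1 repeat control probe set as a covariate, leaving out each sample in turn for the scores and for RNA quality, and the clock list in either direction were added, with an exact test of that list over all splits that allows for its choice among the 26 lists.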

Results

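Gene expression was measured in 4 pancreatic islet samples of lean rats fed standard chow and 5 of obese rats fed a cafeteria diet. The cafeteria diet, given for 30 days, is an energy-dense choice of palatable human foods. The comparison asks which genes of the islets differ between the diets. The arrays resembled each other closely, with correlations over all tested probe sets between 0.979 and 0.994. The mean correlation was 0.987 both between arrays of the same group and between arrays of different groups. The first principal component held 34.4% of the variance and the second 16.7%, and neither differed between the diets by more than the spread between arrays (exact permutation p = 0.254 and 0.317, n = 4 and 5).

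The hormone genes of the islet were among the brightest on the arrays, with Ins2 holding the highest single value (14.24), so that saturation of the probes can hide differences in them. The insulin genes Ins1 and Ins2 differed by 0.0076 (SE 0.0568) and -0.0047 (SE 0.0606) on the log2 scale, with 95% intervals from -0.118 to 0.133 and from -0.139 to 0.129. Iapp, which encodes amylin, differed by 0.0598 (SE 0.0579), the glucose transporter gene Slc2a2 by -0.0245 (SE 0.0709), and the transcription factor gene Mafa by 0.0494 (SE 0.0781). Gcg (glucagon) differed by -0.0777 (SE 0.0793), Sst (somatostatin) by -0.27 (SE 0.17), Ppy (pancreatic polypeptide) by -0.20 (SE 0.14) and Pdx1, a master regulator of the beta cell, by -0.25 (SE 0.14). None of these 9 genes passed the test by limma, and the sign of Ins1, Ins2 and Slc2a2 changed between scalings or with single samples left out, so no direction is given for them. Gcg and Mafa moved by over 1.5 times with single samples left out. Without cafeteria replicate 3 Sst differed by -0.13 and Ppy by -0.0975.

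No single gene passed the threshold in either direction. By limma, 0 of 31042 probe sets and 0 of 14217 genes reached an adjusted p of 0.05 or 0.10, and the smallest adjusted p was 0.844. The number of probe sets at unadjusted p under 0.05 was 1789, with 1023 higher and 766 lower in cafeteria islets, where 1552 are expected by chance. The count was 2712 without lean replicate 1, 2750 without cafeteria replicate 1 and 3413 with RNA quality as a covariate. Both groups were fully separate in 620 probe sets, 2.00% of those tested, where chance gives 1.59%.

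The genes with the smallest p and higher values under the cafeteria diet included the clock repressor Cry1 (0.85, SE 0.18), the trypsinogen genes Prss3bl1 (0.64, SE 0.12) and Prss3 (0.53, SE 0.12), which are related in sequence, and Lrrc59 (0.47, SE 0.11). Also among these 12 were Cptp (0.46), a ceramide-1-phosphate transfer protein, Ghr (0.43, SE 0.09), the growth hormone receptor, Cks1b (0.42, SE 0.08), a subunit of cyclin-dependent kinases, and Crat (0.23), carnitine acetyltransferase. Shisal1 (0.48), Tbl2 (0.44), Ccdc127 (0.37) and Ptrh2 (0.34) completed them. On the lower side stood the nuclear receptor and clock repressor Nr1d1 (-1.36, SE 0.32), the immunoglobulin heavy chain gene Ighl2 (-0.83, SE 0.16), the phosphodiesterase Pde2a (-0.64, SE 0.15), Gpr146 (-0.62), Arhgap4 (-0.53), Tff3 (-0.50), a trefoil peptide, Proser2 (-0.49), Plpp3 (-0.47), Tnfsf10 (-0.43), a death ligand, Gfod2 (-0.40), Tox (-0.32; its other probe set had the opposite sign) and Clec11a (-0.32). In each of these 24 genes every cafeteria array lay on the same side of every lean array, in Gpr146 only just, with lean replicate 1 and cafeteria replicate 1 both at 5.46, but their adjusted p was 0.844.

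Of 26 gene lists, 12 passed camera, 4 with higher and 8 with lower values under the cafeteria diet. With a correlation estimated for each list 0 of the 12 calls held, and with the exact test of the list scores adjusted over the lists 0 held. Without lean replicate 1 camera called 7 lists. At an unadjusted exact permutation p under 0.05 there were 6 lists, of which 5 were among the called. No list had a member past the threshold over all genes. Every statement below on a called list rests on camera at its preset correlation.

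**Figure D1:**
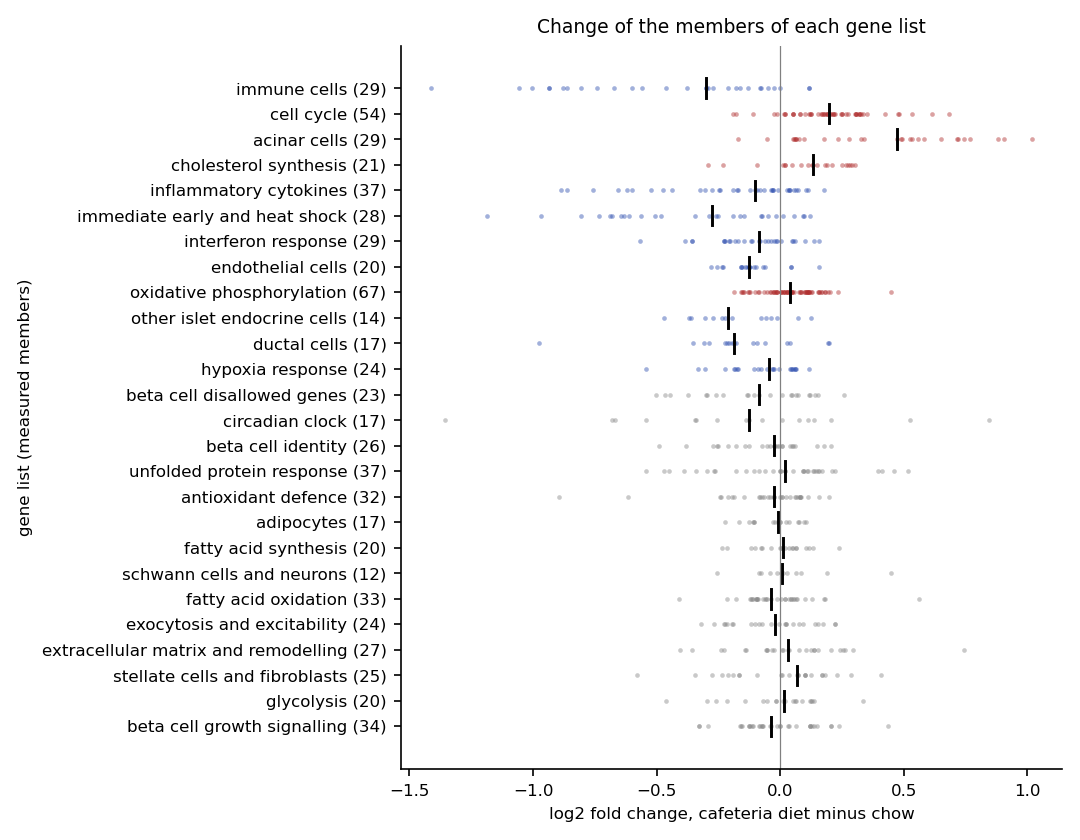
Log2 fold changes (cafeteria diet minus chow, horizontal axis) of the measured members of 26 gene lists, 1 point per gene, with the black line at the list's median; lists are ordered by camera p, with called lists in red (higher, 4) or blue (lower, 8) and the others in grey. The medians of the called lists run from -0.30 for immune cells to 0.47 for acinar cells.

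Genes of pancreatic acinar cells, which make digestive enzymes, were higher under the cafeteria diet in 27 of 29 measured members, with a median of 0.47 (camera adjusted p = 1.04e-06; adjusted p = 0.438 with an estimated correlation). Adjusted over the list alone, 1 member passed, Prss3 (adjusted p = 0.0274). Prss2 differed by 1.02 (SE 0.27), Cuzd1 by 0.33 (SE 0.13) and Bhlha15, a transcription factor of secretory cells, by 0.28 (SE 0.12). Prss3, Prss2 and Cuzd1 were dim in lean samples, with means of 4.75, 4.28 and 4.59, below the array medians of 5.28 to 5.32. The lean mean of Bhlha15 was 7.15. The acinar score was -0.22 ± 0.35 (SD, n = 4) in lean and 0.18 ± 0.53 (n = 5) in cafeteria samples, a difference of 0.40 (exact permutation p = 0.206). Cafeteria replicate 5 had the lowest score of all arrays, -0.74, and without it the difference was 0.63 (exact p = 0.0286).

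Cell cycle genes were higher in 49 of 54 members, with a median of 0.20 (camera adjusted p = 6.10e-08; adjusted p = 0.497 with an estimated correlation), and 0 passed over the list alone. The members with the smallest p were the mitotic motor genes Kif20a (0.62, SE 0.22) and Kif11 (0.43, SE 0.18), Ccne1 (0.27, SE 0.11), a cyclin that drives entry into S phase, and Dlgap5 (0.32, SE 0.13). The list score was -0.11 ± 0.12 (SD, n = 4) in lean and 0.09 ± 0.26 (n = 5) in cafeteria samples (exact permutation p = 0.206). It was not raised in every cafeteria sample: replicate 5 had 0.40 and replicate 3 had 0.24, but replicate 1 had -0.30, the lowest of all arrays. The difference of 0.20 was 0.30 without cafeteria replicate 1 (exact p = 0.0286) and 0.13 without cafeteria replicate 5 (exact p = 0.371).

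Genes of cholesterol synthesis were higher in 18 of 21 members, with a median of 0.13 (camera adjusted p = 2.70e-04; adjusted p = 0.294 with an estimated correlation). The members with the smallest p were Hsd17b7 (0.30, SE 0.10), Stard4 (0.28, SE 0.09; 1 of its other probe sets had the opposite sign), Dhcr7 (0.25, SE 0.09) and Fdps (0.18, SE 0.07), and 0 passed over the list alone. The score was -0.0619 ± 0.0619 (SD, n = 4) in lean and 0.0495 ± 0.0171 (n = 5) in cafeteria samples. It was higher in 5 of 5 cafeteria samples than in any lean sample, at the smallest p of the exact test (0.00794; adjusted over the lists, 0.103).

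Genes of oxidative phosphorylation, the respiratory chain of mitochondria, were higher in 45 of 67 members with a small median of 0.0409 (camera adjusted p = 0.0135; adjusted p = 0.654 with an estimated correlation). Cox5a differed by 0.45 (SE 0.16), Cyc1 by 0.23 (SE 0.09), Ndufa9 by 0.18 (SE 0.07; its other probe set had the opposite sign) and Sdha by 0.16 (SE 0.07). The score was -0.0223 ± 0.0574 (SD, n = 4) in lean and 0.0178 ± 0.111 (n = 5) in cafeteria samples (exact permutation p = 0.556). Cafeteria replicate 3 had the lowest score of all arrays, -0.17, although Cox5a, Cyc1 and Ndufa9 had their highest values in it. The camera call was lost without lean replicate 1 (adjusted p = 0.234) or without cafeteria replicate 1 (0.303), 2 (0.0513) or 4 (0.0809), and with RNA quality as a covariate (0.197).

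**Figure D2:**
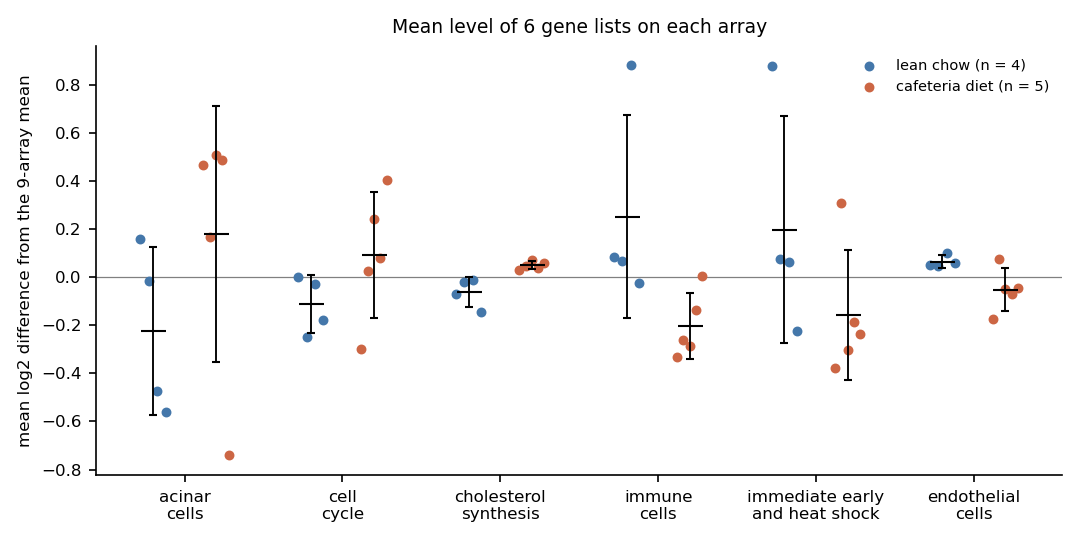
Score of 6 called lists on each array (vertical axis, mean log2 difference from the 9-array mean) in lean (blue, n = 4) and cafeteria-fed (orange, n = 5) samples, with mean and SD in black. Lean replicate 3 stands out for immune cells (0.88), lean replicate 1 for immediate early and heat shock genes (0.88) and cafeteria replicate 5 for acinar cells (-0.74), whereas the cholesterol scores of the groups do not overlap.

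Markers of immune cells were lower in 27 of 29 members, with a median of -0.30 (camera adjusted p = 2.36e-09; adjusted p = 0.294 with an estimated correlation; exact permutation p of the score = 0.0238). The largest of the rule's examples were Coro1a (-1.41, SE 0.46), an actin-binding protein of leukocytes, and Cd74 (-1.01, SE 0.26), the invariant chain of class 2 histocompatibility molecules, with RT1-Db1 (-0.86, SE 0.29) and RT1-Da (-0.81, SE 0.27), which encode such molecules. Lean replicate 3 had by far the highest score, 0.88, against 0.0829 for the next lean sample. Without it Coro1a differed by -0.78, RT1-Db1 by -0.57 and the score by -0.24, in place of -0.45. The exact p of the score was 0.0536 to 0.0571 without any of 5 samples, lean replicate 3 and cafeteria replicates 1, 2, 3 and 4. Split into classes after these values were seen, 20 lymphoid markers differed by -0.55 in their mean (exact permutation p = 0.00794), 13 macrophage markers by -0.18 (exact p = 0.0873) and 8 class 2 histocompatibility genes by -0.50 (exact p = 0.0238). Lymphoid markers of lean replicate 3 stood 1.21 above the 9-array mean, and without this sample the lymphoid difference was -0.25 (exact p = 0.0179) and that of class 2 genes -0.33 (exact p = 0.0714). The exact p of class 2 genes was over 0.05 without any of 7 samples (0.0536 to 0.0714), all but lean replicate 4 and cafeteria replicate 5. Their differences were then -0.33 to -0.55. For macrophage markers the exact p was 0.0286 without cafeteria replicate 5.

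**Figure D3:**
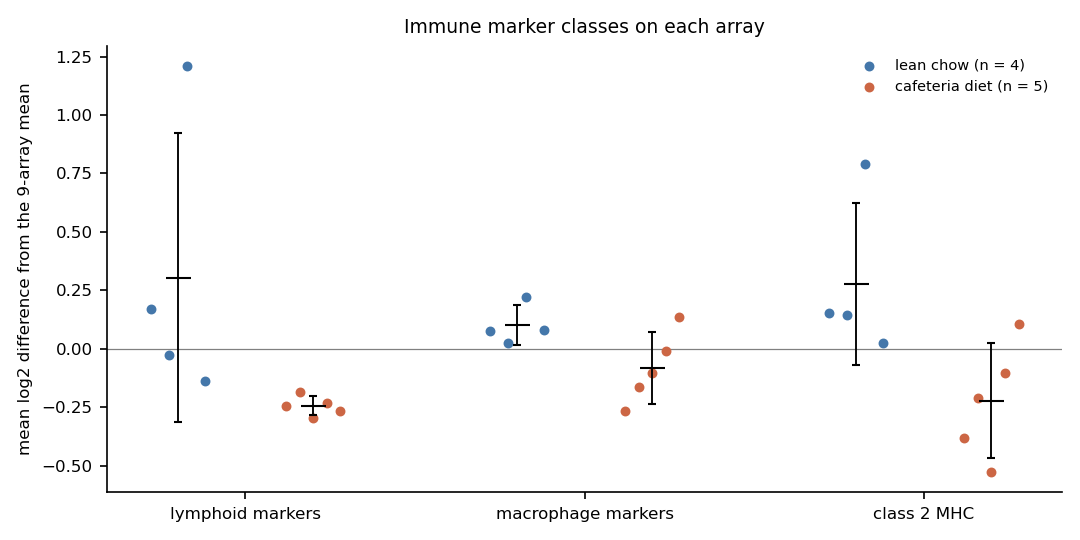
Mean level of 20 lymphoid, 13 macrophage and 8 class 2 histocompatibility (class 2 MHC) genes on each array (vertical axis, mean log2 difference from the 9-array mean) in lean (blue, n = 4) and cafeteria-fed (orange, n = 5) samples, with mean and SD in black. The lymphoid scores of cafeteria samples lie between -0.29 and -0.18, below every lean sample, of which replicate 3 is at 1.21.

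Genes of inflammatory cytokines and their targets were lower in 27 of 37 members, with a median of -0.10 (camera adjusted p = 3.30e-04; adjusted p = 0.294 with an estimated correlation). Examples were Vcam1 (-0.86, SE 0.31) and Icam1 (-0.44, SE 0.14), adhesion molecules for leukocytes, Tnfaip3 (-0.62, SE 0.23), an inhibitor of NF-kB signalling, and the chemokine Ccl7 (-0.52, SE 0.18). Without lean replicate 3 Vcam1 differed by -0.45 and Ccl7 by -0.32, and without lean replicate 1 Tnfaip3 differed by -0.40. The score of lean replicate 1 was 0.34 and that of lean replicate 3 was 0.18, and without these 2 samples, left out after the data were seen, the adjusted p was 0.155. It was 0.190 among the brighter probe sets alone. The score of this list differed by -0.21 (exact permutation p = 0.0397). That exact p was 0.0893 to 0.143 without any single sample but lean replicate 4. In those cases, with fewer splits, the score differed by -0.13 to -0.23. Interferon response genes were lower in 22 of 29 members, with a median of -0.0865 (camera adjusted p = 7.23e-04; adjusted p = 0.294 with an estimated correlation), among them Irf1 (-0.38, SE 0.13), Psmb8 (-0.36, SE 0.11), Mx1 (-0.36, SE 0.13; -0.20 without lean replicate 3) and Gbp2 (-0.20, SE 0.08). This call was lost without lean replicate 4 (adjusted p = 0.0664).

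Immediate early and heat shock genes, which respond quickly to handling and stress, were lower in 23 of 28 members, with a median of -0.27 (camera adjusted p = 4.49e-04; adjusted p = 0.497 with an estimated correlation). Zfp36 differed by -0.80 (SE 0.33), Junb by -0.64 (SE 0.27), the gene Myc by -0.61 (SE 0.28; -0.33 without lean replicate 3 and 0.0306 without lean replicates 1 and 3) and Ier2 by -0.51 (SE 0.27; -0.25 without lean replicate 1). The score of lean replicate 1 was 0.88, and without this sample the call was lost (adjusted p = 0.367). The same sample had a score of 0.62 for ductal cells. Ductal markers were lower in 13 of 17 members with a median of -0.19 (camera adjusted p = 0.0376; adjusted p = 0.566 with an estimated correlation), including Krt8 (-0.31, SE 0.12), Krt7 (-0.22, SE 0.14; -0.11 without cafeteria replicate 3) and Anxa3 (-0.35, SE 0.19; -0.21 without lean replicate 1 and -0.22 without cafeteria replicate 1; 1 of its other probe sets had the opposite sign), whereas Slc4a4 differed by 0.20 (SE 0.11). The ductal call turned its direction and was lost without lean replicate 1 (adjusted p = 0.940), and it was also lost without lean replicate 2 (0.0582) or cafeteria replicate 1 (0.146) or 2 (0.0512), with array weights (0.372) and with RNA quality as a covariate (0.167).

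Endothelial markers were lower in 17 of 20 members, with a median of -0.13 (camera adjusted p = 0.00128, and adjusted p = 0.294 with an estimated correlation). The exact permutation p of the score was 0.0397, and 0.107 to 0.125 without any single sample but cafeteria replicate 2. In those cases, with fewer splits, the score differed by -0.0864 to -0.124, against -0.117 with all samples. Icam2 (-0.24, SE 0.11; -0.16 without lean replicate 3; another probe set had the opposite sign), Tie1 (-0.23, SE 0.10), Flt1 (-0.16, SE 0.09) and the gene Cldn5 (-0.25, SE 0.15; -0.10 without lean replicate 1, -0.41 without lean replicate 2 and 0.0205 without lean replicates 1 and 3) had the smallest p, and the call was lost without cafeteria replicate 1 (adjusted p = 0.0582). Markers of islet cells other than beta cells were lower in 12 of 14 members, with a median of -0.21 (camera adjusted p = 0.0205; adjusted p = 0.45 with an estimated correlation). Beside Sst they included Rbp4 (-0.47, SE 0.17), Irx1 (-0.37, SE 0.17; its other probe set had the opposite sign) and Pyy (-0.30, SE 0.20; -0.12 without cafeteria replicate 3), and the call was lost without lean replicate 1 (adjusted p = 0.234) or cafeteria replicate 5 (0.0585) and with array weights (0.0507). Hypoxia response genes were lower in 16 of 24 members with a median of -0.0447 (camera adjusted p = 0.0463; adjusted p = 0.294 with an estimated correlation), led by Egln3 (-0.54, SE 0.16; -0.35 without lean replicate 2), with Higd1a (-0.30, SE 0.14), Hif1a (-0.18, SE 0.09; -0.12 without lean replicate 3) and Adm (-0.17, SE 0.08). The hypoxia call was lost when any of 6 samples was left out, lean replicates 1 (adjusted p = 0.0874) and 2 (0.173) and cafeteria replicates 1 (0.0685), 2 (0.0870), 4 (0.0827) and 5 (0.0534), and with median centring (0.0507), repeated quantile normalization (0.0579), the brighter probe sets alone (0.209) or the acinar score (0.0560) or RNA quality (0.111) as a covariate.

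Genes of the circadian clock differed in both directions. Adjusted over the list alone, 6 of 17 members passed, more than in any other list, although 0 passed over all genes. The repressors Cry1 (0.85, SE 0.18; adjusted p over the list = 0.0126) and Per2 (0.52, SE 0.16; 0.0241) were higher. Nr1d1 (-1.36, SE 0.32; 0.0133), its relative Nr1d2 (-0.67, SE 0.18; 0.0230), the output gene Dbp (-0.68, SE 0.21; 0.0241) and Npas2 (-0.34, SE 0.10; 0.0230), which pairs with Bmal1, were lower. Per2, Nr1d2, Dbp and Npas2 lie outside the rule and were chosen after their values were seen, as was the test of the list in either direction. The planned list score differed by -0.15, without overlap between the groups, at the smallest p of the exact permutation test (0.00794, adjusted over the lists 0.103). Its exact p was 0.0714 without lean replicate 1, 2 or 4. Camera, which tests for a shift one way, did not call the list (adjusted p = 0.188), whereas fry in either direction gave an adjusted p of 0.0116. That p rose to 0.162 with the acinar score as a covariate, with which the 6 genes kept a median of 92.5% of their differences. It passed the threshold no longer without lean replicate 1 (0.0518), 2 (0.146) or 4 (0.0576) or cafeteria replicate 3 (0.0591) or 4 (0.145). The count of 6 genes fell to 3 without lean replicate 2 or 4 or cafeteria replicate 4, to 2 without cafeteria replicate 3, and to 1 with the acinar covariate.

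**Figure D4:**
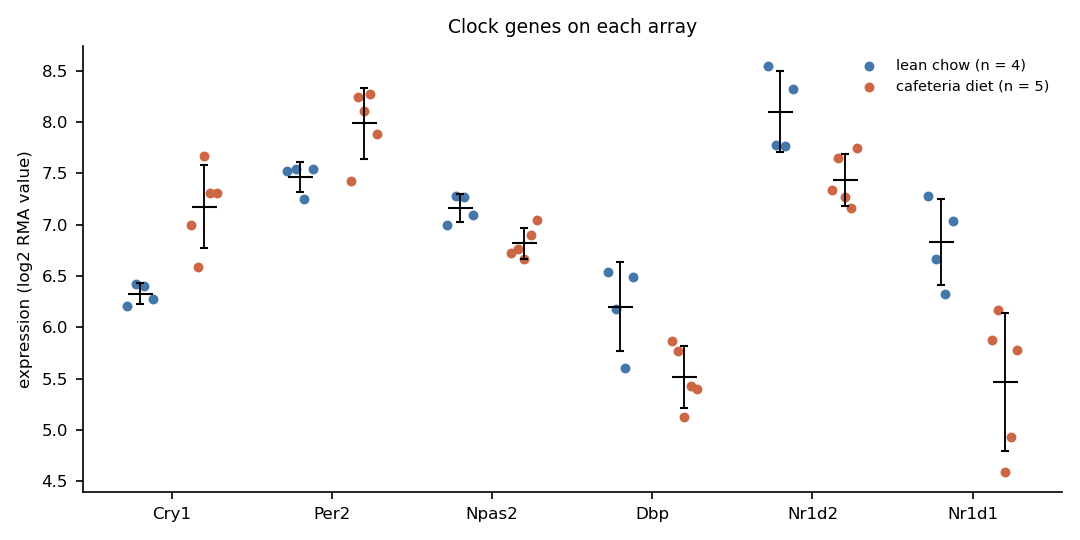
Expression of 6 clock genes on each array (vertical axis, log2 RMA value) in lean (blue, n = 4) and cafeteria-fed (orange, n = 5) samples, with mean and SD in black. Nr1d1 averages 6.83 in lean and 5.47 in cafeteria samples and Cry1 6.33 and 7.17, without overlap between the groups; the 6 genes are those past the threshold over the clock list alone.

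The other lists were not called. The beta cell identity list had 17 of 26 members lower and a median of -0.0252 (camera adjusted p = 0.194), and the members with the smallest p were Isl1 (-0.49, SE 0.20), Gipr (-0.38, SE 0.18; -0.23 without cafeteria replicate 3), Glp1r (-0.27, SE 0.14) and Chgb (0.21, SE 0.09). Genes normally kept silent in beta cells were lower in 13 of 23 members, with a median of -0.0855 (camera adjusted p = 0.0782). This p fell under the threshold, with the list still lower, without lean replicate 2 (0.0428) or 4 (0.0170) or cafeteria replicate 3 (0.0348), 4 (0.0403) or 5 (0.0490). It did so too with the mean over the probe sets of a gene (0.0197). The growth signalling list was not shifted (adjusted p = 0.891), but Ghr passed over that list alone (adjusted p = 0.0252). The unfolded protein response had an adjusted p of 0.270 and antioxidant defence 0.540. Fatty acid synthesis, fatty acid oxidation, glycolysis, exocytosis, matrix remodelling, adipocytes, stellate cells, and Schwann cells with neurons shared an adjusted p of 0.83. Among their markers were Acta2 (-0.58, SE 0.17), Des (-0.23, SE 0.12), Fn1 (0.41, SE 0.27) and Dcn (-0.17, SE 0.12) of stellate cells and fibroblasts, Fabp4 (-0.22, SE 0.16), Aqp7 (-0.12, SE 0.10), Lpl (-0.10, SE 0.09) and Slc2a4 (0.11, SE 0.09; its other probe set had the opposite sign) of adipocytes, and Nefm (0.45, SE 0.17), Mbp (-0.25, SE 0.14), S100b (0.19, SE 0.11) and Ngfr (-0.0859, SE 0.0720) of neurons and Schwann cells. Of these 12, Des, Fn1, Dcn, Fabp4, Aqp7, Lpl, Slc2a4, S100b and Ngfr moved by over 1.5 times with a single sample left out. For stellate cells the median was 0.0662, but the mean (-0.0053) and the test pointed lower. For glycolysis the median was 0.0152 and the test pointed higher, but the mean was -0.0201. Without cafeteria replicate 1 the stellate list turned higher (adjusted p = 0.00416), and the matrix list was called too (0.00881).

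Neither measure of RNA quality differed clearly between the diets by the exact permutation test. The 3-prime minus 5-prime difference was 2.16 ± 0.24 (SD, n = 4) against 2.15 ± 0.33 (n = 5) for actin (exact permutation p = 0.952) and 0.95 ± 0.09 against 0.86 ± 0.16 for Gapdh (exact permutation p = 0.333). Over the 9 arrays their mean was highest in lean replicate 1 (1.80) and lowest in cafeteria replicate 1 (1.21). Leaving out either of these samples raised the number of probe sets at an unadjusted p under 0.05, for a cause that was not tested. The mean was related to the first principal component, with Pearson's r = -0.745 (exact permutation p = 0.0237) and Spearman's rho = -0.700 (exact p = 0.0433). Adjusted over the 6 relations computed, the p of r was 0.142. Without the 2 arrays farthest from the median r was -0.623 over 7 arrays (exact p = 0.131), and within the groups it was -0.858. The cell cycle score had r = 0.662 with RNA quality (exact p = 0.0520; adjusted 0.156), rho = 0.583 (exact p = 0.108), r = 0.670 without the 2 farthest arrays (exact p = 0.0964) and 0.833 within the groups.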

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

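The counts over other splits of the samples into 4 and 5 for genes, probe sets and gene lists were planned, and the other tests in this part were chosen after the result was seen.

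In 10 of 244 groups of samples tested, 1 sample lay far from the others of its group, where chance gives about 1 in 20. The acinar score of cafeteria replicate 5 was -0.74, against 0.17 to 0.51 in the other cafeteria samples. The immune score of lean replicate 3 was 0.88, against -0.0247 to 0.0829 in the other lean samples. In the same sample Coro1a was at 8.09 on the log2 scale, against 5.31 to 5.72, and RT1-Db1 at 7.56, against 6.33 to 6.45. The inflammatory cytokine score of cafeteria replicate 1 was -0.16, against -0.0862 to -0.0591. The antioxidant score of cafeteria replicate 3 was -0.15, against -0.0134 to 0.0254. The immediate early and heat shock score of cafeteria replicate 2 was 0.31, against -0.38 to -0.19. Cuzd1 was at 4.83 in lean replicate 1, against 4.49 to 4.54. Bhlha15 was at 7.09 in cafeteria replicate 2, against 7.48 to 7.59. Irf1 was at 7.74 in lean replicate 4, against 8.06 to 8.07.

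Chance is not excluded for the numbers of genes, probe sets or gene lists called. Few splits reached the number of lists at the preset correlation, which says nothing of any single list. With the real split included, 4 of 100 splits drawn gave as many lists as the diets did, where the real value and the highest of the other splits were both 12, and the median of the others was 7. Without lean replicate 1 the diets gave 7 lists as well, and with an estimated correlation, directional fry or the exact test 0. The number of probe sets at an unadjusted p under 0.05 was reached by 25 of 100 splits, with 1789 for the diets and 5918 for the highest other. For genes past the threshold the diets gave 0, so 100 of 100 splits gave as many, and the highest other gave 48.

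The clock genes Nr1d1, Nr1d2, Dbp and Npas2 were lower and Cry1 and Per2 higher under the cafeteria diet, and 3 of all 126 splits gave as large a mean squared statistic over the clock list (6.47 for the diets, 8.58 for the highest other; exact permutation p = 0.0238), but in 30 of them at least 1 of the 26 lists stood out as much (exact p = 0.238), so chance is not excluded. The 3-prime minus 5-prime difference, the measure of RNA quality, differed little between the diets (-0.0516, exact permutation p = 0.746). As a covariate it could therefore take up little of a difference between them, so its result is no further test of RNA quality as a cause. With it the 6 genes kept a median of 102% of their differences (94.4 to 104) and the list kept an adjusted p of 0.00822 by limma's fry. Acinar content cannot be told apart as a cause. With the acinar score as a covariate each of the 6 genes kept a 95% interval without 0, and they kept a median of 92.5% (76.1 to 109). Nr1d1 went from -1.36 (SE 0.32) to -1.24 (SE 0.37) and Npas2 from -0.34 (SE 0.0978) to -0.26 (SE 0.0975). But these genes were picked for passing over the list in the same samples, and the list's adjusted p by fry rose to 0.162. A different hour of killing and a shift of the clock by the diet cannot be told apart, because the labels give no hour. Nr1d1 and Cry1 deviated in opposite directions within the groups (r = -0.840 over 9 samples), which can occur under either and so does not separate them. A shift of the islet clock by the diet therefore remains a hypothesis.

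Lymphoid markers were lower under the cafeteria diet, and lymphoid tissue carried along with the islets of lean replicates 1 and 3 cannot be told apart from a difference between the diets. Without these 2 samples 29.8% of the lymphoid difference was left (-0.55 to -0.16; exact permutation p = 0.0476, the smallest that 21 splits allow), but they hold the 2 highest lean scores, so the loss does not count for this explanation. Of the 20 lymphoid markers 4 are also in the immune list. Lck, with the brightest probe set among the 20, was at 6.34 ± 0.70 (SD) in lean and 5.78 ± 0.12 in cafeteria samples. In lean replicate 3 it was at 7.37, against 5.92 to 6.11 in the other lean samples. The labels name no sorting step. For macrophage markers, all 13 of them in the immune list, 73.7% was left (-0.13; exact p = 0.286), and for class 2 histocompatibility genes, 4 of 8 in that list, 61.4% (-0.31; exact p = 0.190), which leaves the same 2 explanations open. Fewer immune cells in islets under the cafeteria diet was not tested as a biological explanation.

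Cholesterol synthesis genes were higher by 0.11 in their score, with 5 of 5 cafeteria samples above all lean samples. With the acinar score as a covariate the difference was 0.109 (95% interval 0.0252 to 0.193), against 0.111 without it. But the list was taken up here for its separate scores in the same samples. The acinar score itself did not differ clearly between the diets (exact permutation p = 0.206). The interval therefore does not decide whether acinar content is a cause. With RNA quality as a covariate the difference in the cholesterol score was 0.115 (0.0432 to 0.186), but RNA quality differed little between the diets, so this is no further test of it. The hour of killing, the feeding state and any batch are not in the labels and were not tested, and the exact test adjusted over the lists gave 0.103. An effect of the diet on sterol synthesis may be put forward only as a hypothesis.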

How the results depend on the processing

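Leaving out lean replicates 1 and 3 together, fry in either direction, the B1 repeat control as a covariate, list scores and the RNA quality difference with single samples left out and every test of the clock list in either direction or over its own genes were chosen after the data were seen. Under each alternative run, limma called 0 genes and 0 probe sets, while the probe sets at an unadjusted p under 0.05 ranged from 899 to 3413 (1789 as reported). None of 1876 values of the 95 named genes passed, and 16 of them, in 6 genes, changed sign. With 1 sample left out, 32 of the 95 genes moved by over 1.5 times. Of the 12 called lists, 5 (immune cells, cell cycle, acinar cells, cholesterol synthesis and inflammatory cytokines) were called with each of the 9 samples left out. The number of called lists was 0 with an estimated correlation, 0 with directional fry, 0 with the exact permutation test, 1 with fry in either direction (the clock list) and 6 without lean replicates 1 and 3. With single samples left out it ranged from 7 (without lean replicate 1) to 13 (without cafeteria replicate 3). It lay between 9 and 13 with median centring, repeated quantile normalization, the filter on dim probe sets, the intensity trend, array weights, the acinar, RNA quality and B1 covariates and the mean over probe sets. The acinar list was not called with its own score as the covariate (adjusted p = 0.763), by construction. The ductal list turned its direction without lean replicate 1 (adjusted p = 0.940; other samples left out, from 8.85e-04), and the stellate list without cafeteria replicate 1 (0.00416; others up to 0.868). The adjusted p of the clock list in either direction was 0.162 with the acinar covariate, 0.393 without lean replicates 1 and 3, and 4.91e-05 (without cafeteria replicate 1) to 0.146 (without lean replicate 2) with single samples left out. The count of clock genes was 1 with the acinar covariate and 2 (without cafeteria replicate 3) to 8 (without cafeteria replicate 1) with single samples left out. The difference in RNA quality ranged from -0.11 (without cafeteria replicate 3) to 0.0281 (without lean replicate 1). Leaving out samples lowers the number compared, and beyond that, as for the acinar covariate, the cause was not tested. No paired analysis was possible because the replicate numbers follow the order of the samples and pair none of them. RMA values hold no background measure per probe set, so how far dim signals limit these results is known only from the filter on dim probe sets, with 10 lists called.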

Other observations

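The genes in this part were chosen after their values were seen, as was the split of the samples described last. Genes of the unfolded protein response went both ways, and the list was not called (camera adjusted p = 0.270). The 5 members at an unadjusted p under 0.05 by limma were Dnajb11 at 0.52 (SE 0.17), Derl2 at 0.41 (SE 0.15), Creld2 at 0.46 (SE 0.17), Sesn2 at -0.29 (SE 0.13) and Ppp1r15a at -0.45 (SE 0.20), and 0 passed over the list alone. Ppargc1a, a coactivator of mitochondrial genes, differed by 0.56 (SE 0.18), and the glycolysis genes Pfkp and Ldha by 0.33 (SE 0.11) and -0.29 (SE 0.10). None of these genes passed over all genes.

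Albumin (Alb) had the probe set with the smallest unadjusted p of all, with a difference of 0.67 (SE 0.0986; adjusted p = 0.844 by limma) from a dim lean mean of 4.25, and its other probe set differed by 1.16 (SE 0.31). Of the immunoglobulin genes, Ighvl1 differed by -2.10 (SE 0.62), with 9.02 in lean replicate 3 against 6.01 in the next lean sample, and Jchain by -0.64 (SE 0.21). Iglc1 differed by -0.27 (SE 0.18), with 5.14 in lean replicate 3 against 4.39 in the next lean sample. Of these genes 0 passed the threshold. The unnamed probe set with the smallest p differed by -3.17 (SE 0.51), from 7.48 ± 1.36 (SD) in lean to 4.31 ± 0.32 in cafeteria samples. The Reg family of regeneration proteins, too few to test as a list, had Reg3a at 0.71 (SE 0.49), Reg3b at 0.45 (SE 0.53), Reg1a at 0.35 (SE 0.34) and Reg3g at 0.0824 (SE 0.11).

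Of the 100 splits drawn, that of lean replicates 1 and 4 and cafeteria replicates 2 and 5 from the other 5 samples gave the most genes past the threshold, 48, in 149 probe sets. The split was picked for its count, so neither the count nor these probe sets are a test of a structure of the samples apart from diet. Of the probe sets, 107 were higher in these 4 samples, and 89 of them (83.2%) had no single gene, against 32.9% of all probe sets. The B1 repeat control probe set lay between 5.70 and 5.84 in these 4 samples and between 5.12 and 5.40 in the other 5, and differed between the diets by 0.0156 (exact permutation p = 0.889). With this control as a covariate 12 lists were called, as without it.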
